A study of Mus musculus with 41 samples.

How the data were processed

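The series holds 41 single-colour Affymetrix arrays, 1 per RNA sample, from flow-sorted B cell precursors of C57BL/6 mice with wild-type Pax5. Per the labels, RNA was extracted with Arcturus PicoPure, amplified and labelled with the NuGEN Ovation Pico system and carried a biotin label. The deposited intensity values are MAS5 signals per the submitters' processing notes, which give no version, and they are linear and never negative. On every array the mean without the lowest and highest 2% of probe sets was 500, so the authors had scaled each array to that target. Detection calls were not used here, and the genome build is not given in the sources used here. The populations and replicate numbers were read from the sample titles.

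Of 45101 probe sets, 64 were controls and 35890 were listed by the annotation table, 34958 with 1 gene and 932 with several; 9211 were not listed. For 34754 of the probe sets with 1 gene the Entrez identifier was found in the gene table, and 0 symbols needed an update. Each of 18194 genes was represented by the probe set with the highest mean, and 11947 genes that reached their array's median on at least 5 arrays were tested. Of these 6018 had several probe sets. Signals were taken as log2(value + 32), which understates the change of genes with low signals. No further normalization was applied. The plan made before the data were examined was to leave the values alone if the array medians showed that they were scaled, and otherwise to use quantile normalization. The trimmed means were equal, but the medians ranged from 69.1 to 153.1, so the plan could be read either way; the authors' scaling was kept, and quantile normalization and median centring were run as alternatives.

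Differences were tested with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend and robust) in R 4.3.3, with statmod 1.5.0 and the data.table package (version 1.17.8). All 41 arrays were in 1 fit with 7 group means, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were A vs CLP, B vs A, C vs B, D vs C, E vs D, F vs E and F vs CLP, each first minus second, and a moderated F-test across the 7 populations. The comparisons, tests, gene lists and most alternatives were chosen before the data were examined. The lists were written from general knowledge: 31 lists with 579 symbols, of which the annotation table did not name 70. They covered sorting markers, hypodiploid leukaemia genes, early progenitors, B lineage transcription factors, the pre-B cell receptor, V(D)J recombination, B cell receptor signalling, mature B cells, MHC class II, interleukin 7 signalling, S phase, G2 and mitosis, cell cycle inhibitors, core histones, ribosome biogenesis and glycolysis. The others were oxidative phosphorylation, cholesterol synthesis, interferon response, immediate early genes, heat shock, trafficking, apoptosis, NF-kappaB, Notch, myeloid, NK and T, erythroid, megakaryocyte, plasmacytoid dendritic and plasma cells. The last 6 are markers of cell types outside the path. The 30 lists with at least 5 tested genes were tested with camera (correlation between genes 0.01) in 7 comparisons, adjusted over 210 tests; core histones had 3 tested genes and were not tested as a list. Symbols that matched only as synonyms (3 symbols in 3 lists) were first accepted and then dropped after list results had been seen; 89 tests passed with them and 89 without, and 0 calls differed.

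Genes named in the text are the 5 that rose most and the 5 that fell most among called genes without overlap between the arrays, up to 2 called members in each direction of a described list, and tested members of the sorting and hypodiploid leukaemia lists. Where a call was lost without single arrays, some of these genes are left out. Alternatives chosen before the data were examined were a pseudocount of 1 or 4 times larger than that used, no filter or a 75th percentile filter, quantile normalization, median centring, the mean of a gene's probe sets, a test of each probe set, and the replicate number as a block. A fit of only the 2 groups compared, array weights, eBayes without trend and robust, an estimated correlation or fry for the lists, and each array left out in turn were also planned. Leaving out A arrays 4, 6 and 7, B arrays 1 and 4, or genes high in E array 2 was added after seeing the data. Leaving out CLP arrays 4 to 7 or E array 2 had also been considered for addition: the first was not run because the arrays would have been chosen by a measured gene, and E array 2 was already among the arrays left out in turn.

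The method was tested on simulated data with 50 genes changed at each of 4 sizes. With each population's own spread, the comparison of A with the CLP recovered 10, 26, 47 and 50 of them at log2 changes of 0.5, 1, 2 and 3. The share of false calls was 55.1% there, 73.1% for B vs A and 15.6% for C vs B, and 1.77% to 8.00% in the other comparisons. Few of the 11947 simulated genes were changed, so these shares do not carry over to the real counts. Of the unchanged genes, 1.39% were called in A vs CLP, 3.01% in B vs A and 0.196% in C vs B. With the pooled spread in every population it was 3.88%, 4.62% and 9.49% in the same order, so unequal spread made most of the false calls in A vs CLP and B vs A, while for C vs B 13 of 137 calls were false without it, against 23 of 147 with it. In simulated data of A vs CLP camera gave a p under 0.05 for a list of 20 genes moved by 0.5 and for 7 of 200 unmoved lists. Genes were drawn independently and put into lists at random there. The rate therefore cannot show how camera behaves on lists of genes that move together.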

Results

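Gene expression was measured on 41 single-colour Affymetrix arrays of RNA from 7 flow-sorted populations of the mouse B cell lineage. The populations were the common lymphoid progenitor (CLP, 7 arrays) and Hardy fractions A (7), B (7), C (5), D (5), E (5) and F (5). The CLP is a progenitor that can still give rise to several lymphoid lineages. In the Hardy scheme, as background, fraction A holds pre-pro-B cells, B holds pro-B cells, C holds late pro-B and large pre-B cells, D holds small pre-B cells, E holds immature B cells and F holds mature recirculating B cells. The labels give neither the sorting gates nor the tissue, and they do not say whether the arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The comparisons follow the path the series describes: each population against the one before it, and the last against the CLP. The number of arrays limits the precision of every value.

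The deposited signals had a median of 69.1 to 153.1 per array. Fraction A stood apart in array quality: its arrays correlated with the rest of their group at 0.781 to 0.885, whereas those of the CLP correlated at 0.948 to 0.967 and those of fraction D at 0.968 to 0.971. The ratio of 3' to 5' Gapdh signal, which rises when RNA is short, was 12.7 ± 9.92 (SD, n = 7) in A, 7.52 ± 2.33 (SD, n = 7) in B, 4.95 ± 1.14 (SD, n = 5) in C and 4.17 ± 0.519 (SD, n = 7) in the CLP. For actin it was not higher in A: 0.849 to 1.26 in A and 1.20 to 1.35 in the CLP. The median SD of a gene on the log2 scale was 0.791 in A, 0.502 in B and 0.254 in D. No 2 arrays held identical values, and the highest correlation of any pair was 0.983. Of 11947 genes tested, 8756 (73.3%) differed among the 7 populations at an adjusted p under 0.05 (limma F-test with Benjamini-Hochberg adjustment). Principal components 1 and 2 held 25.6% and 16.1% of the variance, and the mean position on component 1 was -43.3 in the CLP, -44.2 in A, -17.7 in B, -9.85 in C, 42.8 in D, 55.6 in E and 58.7 in F.

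Single genes are given as log2 difference ± SE, and signals as mean ± SD in the scaled MAS5 units of the submitters. Where the lower of the signals was at or under the array medians, the size of the difference depends on the 32 added before the log, and so does the order of the largest differences. With a pseudocount of 1, for example, Klra8 (7.70) stood above Styk1 (7.40) and Ifng (7.01) in A vs CLP, Lcn2 (7.64) above Chil3 (7.26) in C vs B, and Adgrg3 (-8.14) fell further than Dntt (-7.65) in F vs CLP. Where a gene is said to have risen or fallen, its limma p after Benjamini-Hochberg adjustment over all genes tested was under 0.05. Gene lists were tested with camera in limma, adjusted over 210 tests of 30 lists in 7 comparisons. Of these tests 89 passed, and 35 passed with an estimated correlation between genes. The 5 largest rises and falls of each comparison are genes whose arrays did not overlap between the populations.

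**Figure D1:**
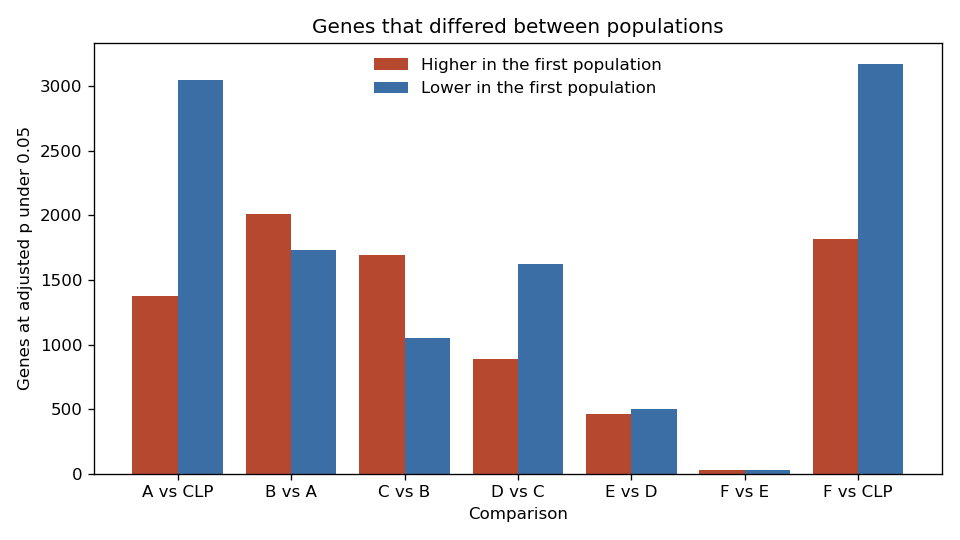
Number of genes called higher (up) and lower (down) in the first named population of each comparison, as bars from 0, at an adjusted p under 0.05 among 11947 genes tested. The counts run from 56 genes between fractions F and E to 4993 between F and the CLP.

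The comparison of fraction A with the CLP asks what differs at the entry to the B cell path. Genes of natural killer (NK) cells were far higher in fraction A: Gzma, a granule protease of cytotoxic lymphocytes, had a signal of 30736 ± 11497 (SD, n = 7) in A and 111 ± 52.4 (SD, n = 7) in the CLP, a log2 difference of 7.76 ± 0.45 (limma adjusted p = 9.41e-18). The CLP signal of Gzma was at the array medians (110.0 to 130.4), and the difference was 8.17 with a pseudocount of 1 and 6.96 with a pseudocount 4 times larger. The other largest rises were Styk1 (5.84 ± 0.31), Ifng (5.67 ± 0.39), the cytokine interferon gamma, Klra8 (5.59 ± 0.29), an NK receptor, and Tmsb15a (5.58 ± 0.41). The largest falls were B lineage genes and others: the kappa light chain segments Igk-V21 (-5.25 ± 0.53) and Igkv9-120 (-4.76 ± 0.48), Scn4b (-4.42 ± 0.40), Ebf1 (-4.34 ± 0.25), a transcription factor that commits cells to the B lineage, and Igll1 (-4.30 ± 0.50), a surrogate light chain of the pre-B cell receptor. Ebf1 had a signal of 197 ± 173 (SD, n = 7) in A against 3692 ± 914 (SD, n = 7) in the CLP.

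Of 18 NK and T cell genes, 10 rose, 3 fell and 5 did not pass, and 11 rose and 3 fell adjusted over the list alone (median 1.18, camera adjusted p = 2.61e-08). The NK receptor gene Ncr1 (5.00 ± 0.32) rose, while the T cell genes Cd3e (-1.14 ± 0.34) and Gata3 (-1.73 ± 0.27) fell, although the call of Cd3e was lost with quantile normalization, a pseudocount of 1 or a fit of these 2 populations alone. Of 14 plasmacytoid dendritic cell genes, 9 rose and 0 fell, with the same counts adjusted over the list alone (median 1.03, camera adjusted p = 3.99e-08). Among these were Cd7 (2.84 ± 0.33) and Cd209d (2.72 ± 0.36). Immediate early genes, which respond to stimulation and to handling, rose for 12 of 20 members, and 13 rose adjusted over the list alone (median 1.12, camera adjusted p = 1.35e-06, and adjusted p = 0.169 with an estimated correlation). Examples were Egr2 (2.31 ± 0.53) and Egr1 (2.16 ± 0.43). Their level varied widely among the CLP arrays, from 8.85 to 10.98, where A ranged from 9.82 to 10.92, so the populations overlapped. Of 18 trafficking genes, 7 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone (median 0.10, camera adjusted p = 0.0201, and adjusted p = 0.130 with an estimated correlation). Its median was close to 0 and unsteady: -0.024, 0.18 and 0.21 without A array 3, 4 or 6, 0.16, 0.017, 0.047 and 0.21 without CLP array 1, 2, 5 or 7, and 0.33 with median centring. The integrins Itgb1 (1.94 ± 0.27) and Itgal (1.62 ± 0.17) rose, and Ccr7 (-2.12 ± 0.33), a receptor that guides cells into lymph nodes, fell. Of 9 heat shock genes 4 rose, also adjusted over the list alone, with Hspa8 (1.30 ± 0.17) and Hspa5 (0.92 ± 0.16) among them (median 0.29, camera adjusted p = 7.90e-04, and adjusted p = 0.0843 with an estimated correlation). With quantile normalization Hspa8 and Hspa5 stood at 0.12 and 0.35 and the list at 0.01 (adjusted p = 0.946), and with median centring the list stood at 0.52. The list median of 0.29 was 0.51 without A array 4, 0.44 without A array 7 and 0.55 without CLP array 3.

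Genes of the pre-B cell receptor fell for 9 of 11 members, and 9 fell adjusted over the list alone (median -1.71, camera adjusted p = 1.56e-06). V(D)J recombination genes fell for 9 of 13, and 9 fell adjusted over the list alone (median -0.93, camera adjusted p = 0.0148), including the recombinase genes Rag1 (-1.80 ± 0.28) and Rag2 (-2.11 ± 0.27). Of 19 B lineage transcription factors 10 fell and 3 rose, and 4 rose and 11 fell adjusted over the list alone (median -0.62, camera adjusted p = 0.0415, and adjusted p = 0.335 with an estimated correlation). That call was lost without CLP array 7 (adjusted p = 0.0548) or without A array 2, 3, 5 or 6 (adjusted p = 0.0645, 0.0636, 0.0743 and 0.102). It was also lost in a fit of these 2 populations alone (adjusted p = 0.106), with a pseudocount of 1, under the 75th percentile filter, with the replicate number as a block and without the trend and robust options, and with median centring the median was -0.39. Pax5 (-3.40 ± 0.29), which maintains B cell identity, and Pou2af1 (-3.82 ± 0.50) fell, whereas Ikzf3 (1.86 ± 0.29) and Irf8 (1.17 ± 0.25) rose. Among genes used in sorting schemes, Ptprc (1.27 ± 0.12), which encodes CD45, rose (0.82 with quantile normalization), and Il7r (-0.93 ± 0.15), Kit (-1.60 ± 0.43) and Cd93 (-1.83 ± 0.18) fell. Markers of other cell types moved apart: 10 of 20 myeloid genes fell and 2 rose, while 3 rose and 11 fell adjusted over the list alone, without the list passing (median -1.05, camera adjusted p = 0.300). Fcer1g and Fcgr3, which NK cells also express, rose by 2.09 ± 0.30 and 1.53 ± 0.33, whereas the granule genes Chil3 (-3.36 ± 0.45) and Camp (-2.50 ± 0.49) fell. The erythroid list had 1 member up and 4 down of 11 (median -0.69, camera adjusted p = 0.207) and the plasma cell list 1 up and 7 down of 12 (median -0.79, camera adjusted p = 0.107), with the same counts adjusted over the list alone, and Jchain (-3.88 ± 0.62) and Sdc1 (-3.59 ± 0.31) fell. The plasma cell list passed with quantile normalization (adjusted p = 0.0155), without a filter on low values (adjusted p = 0.00663), by fry (adjusted p = 2.21e-05) and without CLP array 1 or 3 (adjusted p = 0.0395 and 0.0473), and the erythroid list by fry (adjusted p = 0.00768).

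In this comparison 4424 of 11947 genes passed, 1377 up and 3047 down, of which 556 and 1648 changed at least 2-fold. Of those that passed, 1120 had arrays that did not overlap. Among all 11947 genes tested this held for 1122, against a chance share of 0.0583%. Fraction A was more variable than the populations it shares the estimate of spread with: fitted with the CLP alone, 2418 genes passed, and in simulated data with each population's own spread 163 of 296 calls were false in the 7-population fit and 19 of 125 in the fit of these 2. Those data changed few genes, so the shares do not carry over to the real counts. Of their unchanged genes, 1.39% and 0.162% were called. The median of all genes was -0.22. Centring each array on its median moved it to 0.01 and gave 2071 genes up and 1776 down, so the share of higher genes went from 31.1% to 53.8%, and quantile normalization moved the median to -0.11. Without A arrays 4, 6 and 7 the counts were 1569 up and 2079 down (43.0% up).

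B vs A follows a dip of B lineage genes in A: pre-B cell receptor levels were 11.80 (CLP), 9.63 (A) and 12.41 (B). Ebf1 (5.02 ± 0.25) had a signal of 5822 ± 726 (SD, n = 7) in B and 197 ± 173 (SD, n = 7) in A (limma adjusted p = 6.92e-20). The other largest rises were Bfsp2 (5.05 ± 0.25), Pou2af1 (4.99 ± 0.50), a coactivator of immunoglobulin genes, Igll1 (4.81 ± 0.50) and Cplx2 (4.44 ± 0.59). The NK genes high in A were low in B: Gzma (-6.80 ± 0.45) and Klrk1 (-6.21 ± 0.32), an NK receptor, fell, together with Tmsb15a (-6.36 ± 0.41), Ms4a4b (-6.33 ± 0.38) and the chemokine gene Ccl5 (-6.07 ± 0.37).

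Pre-B cell receptor genes rose for 11 of 11 members, also adjusted over the list alone (median 2.87, camera adjusted p = 3.80e-12). Of the B lineage transcription factors 11 of 19 rose and 2 fell, and 11 rose and 3 fell adjusted over the list alone (median 1.08, camera adjusted p = 3.68e-06). Pax5 (3.39 ± 0.29) and Irf4 (3.83 ± 0.28) rose, and Irf8 (-2.81 ± 0.25) and Klf3 (-1.31 ± 0.25) fell. V(D)J recombination genes rose for 7 of 13, and 9 rose adjusted over the list alone (median 0.82, camera adjusted p = 9.57e-05). Examples were Rag2 (2.78 ± 0.27) and Rag1 (2.69 ± 0.28). The list median of 0.82 was 0.52 without A array 7. B cell receptor signalling genes rose for 12 of 21 and fell for 2, and 13 rose and 2 fell adjusted over the list alone (median 0.69, camera adjusted p = 1.52e-04, and adjusted p = 0.0704 with an estimated correlation). The receptor chains Cd79a (3.62 ± 0.40) and Cd79b (3.27 ± 0.31) rose, and Nfatc1 (-1.47 ± 0.25) and Malt1 (-1.16 ± 0.22) fell. Proliferation genes rose together: 18 of 26 S phase genes (20 rose adjusted over the list alone; median 0.87, camera adjusted p = 1.57e-07) and 22 of 26 genes of G2 and mitosis (23 rose adjusted over the list alone; median 1.08, camera adjusted p = 3.99e-08, and adjusted p = 0.255 with an estimated correlation). Examples were Uhrf1 (1.73 ± 0.17), Mcm10 (2.18 ± 0.43), Cenpf (1.63 ± 0.30) and Kif20a (1.57 ± 0.35). Ribosome biogenesis genes rose for 9 of 21, and 11 rose adjusted over the list alone (median 0.40, camera adjusted p = 0.00260, and adjusted p = 0.164 with an estimated correlation). Among these was Gnl3 (1.16 ± 0.21). Oxidative phosphorylation genes rose for 9 of 24, and 9 rose adjusted over the list alone (median 0.33, camera adjusted p = 0.0203, and adjusted p = 0.326 with an estimated correlation), with Uqcrfs1 (1.20 ± 0.27) among them. The list median of 0.33 was 0.21 without A array 6, and the call was lost without B arrays 1 and 4 (adjusted p = 0.0851) and under the 75th percentile filter (adjusted p = 0.126). With median centring its median was 0.53.

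Of the 6 marker lists of other cell types, 3 passed, each lower in B: 15 of 18 NK and T cell genes fell and 1 rose, and 1 rose and 16 fell adjusted over the list alone (median -3.25, camera adjusted p = 5.48e-18). The member that rose was Cd247 (1.32 ± 0.21), a signalling chain of T cell and NK receptors. Of its 3 other probe sets 2 were called in the opposite direction, and the mean of its probe sets gave -1.06. Plasmacytoid dendritic cell genes fell for 11 of 14, also adjusted over the list alone (median -2.72, camera adjusted p = 2.23e-13). Among these were Siglech (-5.00 ± 0.34) and Cd7 (-4.68 ± 0.33). Myeloid genes fell for 9 of 20, also adjusted over the list alone (median -0.78, camera adjusted p = 9.57e-06, and adjusted p = 0.279 with an estimated correlation). Examples were Csf1r (-3.91 ± 0.65) and Fcer1g (-3.86 ± 0.30). Trafficking genes fell for 8 of 18 and rose for 1, and 1 rose and 9 fell adjusted over the list alone (median -0.63, camera adjusted p = 1.54e-05), with Itgb7 (-3.49 ± 0.25) and Ccr9 (-3.23 ± 0.45) falling. Interferon response genes fell for 6 of 18 and rose for 1, and 1 rose and 7 fell adjusted over the list alone (median -0.58, camera adjusted p = 0.0125, and adjusted p = 0.163 with an estimated correlation), with Bst2 (-2.63 ± 0.20) and Stat2 (-1.64 ± 0.24) falling. This call was lost under the 75th percentile filter (adjusted p = 0.0694). Of the early progenitor genes 7 of 18 fell and 2 rose, and 2 rose and 8 fell adjusted over the list alone (median -0.32, camera adjusted p = 0.0305, and adjusted p = 0.460 with an estimated correlation), with Id2 (-4.53 ± 0.31) and Ctla2a (-3.71 ± 0.34) falling. Its median of -0.32 was -0.49 without A array 4, and the call was lost without A array 1, 2 or 3 (adjusted p = 0.0805, 0.0560 and 0.0540) or B array 1 or 4 (median -0.12 with adjusted p = 0.108, and adjusted p = 0.0570). It was also lost with the mean of each gene's probe sets (adjusted p = 0.0700) and without B arrays 1 and 4 together (median 0.02), and with median centring the median was -0.13. The megakaryocyte list, with 3 of 6 members down (4 adjusted over the list alone), did not pass (median -0.91, camera adjusted p = 0.0528) but passed with median centring (adjusted p = 0.0410), in a fit of these 2 populations alone (adjusted p = 0.0445), with array weights (adjusted p = 0.0480) and by fry (adjusted p = 5.84e-05). It also passed without A array 6 or 7 (adjusted p = 0.0363 and 0.0351) or B array 5 or 6 (adjusted p = 0.0375 and 0.0474). Erythroid genes, with 2 of 11 up and 1 down (median -0.52, camera adjusted p = 0.595), and plasma cell genes, with 4 of 12 up and 2 down (median 0.14, camera adjusted p = 0.182, and adjusted p = 0.00106 by fry), did not pass, with the same counts adjusted over the lists alone. Among sorting markers Cd24a (1.76 ± 0.19) and Cd93 (1.80 ± 0.18) rose while Ptprc (-1.33 ± 0.12) and Flt3 (-1.70 ± 0.40) fell.

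Between A and B 3741 genes passed, 2012 up and 1729 down, with 874 and 957 of at least 2-fold. Of all 11947 genes tested 611 had arrays that did not overlap, all among those that passed, against a chance share of 0.0583%. Fitted without the other 5 populations 1343 genes passed, and in simulated data with each population's own spread 353 of 483 calls were false in the 7-population fit and 7 of 94 in the fit of these 2. As above, the shares do not carry over to the real counts. Of the unchanged genes, 3.01% and 0.0596% were called. Centring each array on its median moved the median of all genes from 0.02 to 0.21 and gave 2937 genes up and 1137 down, a share of higher genes of 72.1% in place of 53.8%. Other alternatives gave more falls than rises: 591 up and 752 down (44.0% up) in the fit of these 2 populations, 1586 and 2115 (42.9%) without A arrays 4, 6 and 7, and 1834 and 1989 (48.0%) without a filter on low values.

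Fraction C against fraction B follows the cells from pro-B to late pro-B and large pre-B cells. The sorting marker Enpep, which encodes the antigen BP-1 that separates C from B in the Hardy scheme, rose from 70.0 ± 64.1 (SD, n = 7) to 2015 ± 794 (SD, n = 5), a log2 difference of 4.45 ± 0.34 (limma adjusted p = 1.04e-12). The largest rises were genes of neutrophils and other myeloid cells: Chil3 (6.02 ± 0.50), Ltf (5.29 ± 0.54), which encodes lactoferrin, Camp (5.13 ± 0.54), Lcn2 (5.09 ± 0.52) and Slfn4 (4.65 ± 0.46). The largest falls were Fos (-2.95 ± 0.52), Rab26os (-2.51 ± 0.34), Grwd1 (-2.25 ± 0.25), Txnrd3 (-2.14 ± 0.54) and Kif23 (-2.10 ± 0.31). Chil3 had a signal of 5129.9 ± 783 (SD, n = 5) in C and 63.4 ± 60.1 (SD, n = 7) in B.

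Myeloid genes rose for 16 of 20, and 18 rose adjusted over the list alone (median 2.68, camera adjusted p = 1.38e-14). Interferon response genes rose for 16 of 18, also adjusted over the list alone (median 1.34, camera adjusted p = 2.26e-09). Among these were Rsad2 (4.40 ± 0.66) and Ifit1 (2.79 ± 0.41). Of the 5 other marker lists of other cell types 2 passed: 7 of 14 plasmacytoid dendritic cell genes rose, and 9 rose and 1 fell adjusted over the list alone (median 1.02, camera adjusted p = 0.00289, and adjusted p = 0.107 with an estimated correlation). Among these were Siglech (2.25 ± 0.37) and Klra17 (2.92 ± 0.60). NK and T cell genes rose for 6 of 18, and 6 rose adjusted over the list alone (median 0.77, camera adjusted p = 0.0144, and adjusted p = 0.314 with an estimated correlation), a call lost without C array 1 (adjusted p = 0.0665) and with a pseudocount 4 times larger (adjusted p = 0.0618). Erythroid genes rose for 5 of 11 and fell for 1, and 6 rose and 1 fell adjusted over the list alone, but the list did not pass with the deposited scaling (median 0.74, camera adjusted p = 0.0600). It passed with quantile normalization (median 0.39, adjusted p = 0.0137), median centring (median 0.32, adjusted p = 0.00566), no filter on low values (median 0.45, adjusted p = 0.0342), a fit of these 2 populations (adjusted p = 0.0293), the replicate number as a block (adjusted p = 0.0300) and fry (adjusted p = 0.00371). Without B array 5 or 6 or C array 4 or 5 it passed as well (adjusted p = 0.0168, 0.0474, 0.0204 and 0.0322). Slc4a1 (4.11 ± 0.53) and Alas2 (3.02 ± 0.46), which serve red cell membranes and haem synthesis, rose. Neither plasma cell genes, with 3 of 12 up and 2 down, and 5 rose and 2 fell adjusted over the list alone (median 0.46, camera adjusted p = 0.630), nor megakaryocyte genes (median 0.33, camera adjusted p = 0.687) passed. MHC class II genes, which present antigen, rose for 6 of 10, and 7 rose adjusted over the list alone (median 1.09, camera adjusted p = 0.00106, and adjusted p = 0.0704 with an estimated correlation). Examples were H2-Eb1 (2.03 ± 0.41) and Cd74 (1.65 ± 0.40). Mature B cell genes rose for 9 of 22 and fell for 1, and 12 rose and 2 fell adjusted over the list alone (median 0.73, camera adjusted p = 0.0305, and adjusted p = 0.229 with an estimated correlation). Ccr7 (1.56 ± 0.36) rose. The mature B cell call was lost without B array 2 (adjusted p = 0.0681) or C array 1, 4 or 5 (adjusted p = 0.0510, 0.0848 and 0.0760) and with a pseudocount of 1 (adjusted p = 0.0542). With median centring the medians were 0.60 for plasmacytoid dendritic cell, 0.35 for NK and T cell, 0.67 for MHC class II and 0.31 for mature B cell genes, and with quantile normalization that of NK and T cell genes was 0.44.

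Lists of growth and proliferation genes were lower in C, but its arrays stood in 2 sets. On the mean log2 level of G2 and mitosis genes, C arrays 1 and 2 (11.66 and 11.69) lay within the range of B (11.24 to 11.82), and C arrays 3, 4 and 5 lay below it (10.62, 10.02 and 10.26). For ribosome biogenesis the levels were 11.64 and 11.59 on C arrays 1 and 2 and 10.92 to 11.05 on the others, against 11.78 to 11.95 in B, and on principal component 1 the positions were -22.2 and -19.8 against -3.76 to -0.94. The fall of the G2 and mitosis genes was thus carried by 3 of the 5 arrays of C, and the cause was not tested. S phase genes fell for 12 of 26 and rose for 1, and 1 rose and 14 fell adjusted over the list alone (median -0.57, camera adjusted p = 1.18e-08). An example was Cdc6 (-1.08 ± 0.18). Genes of G2 and mitosis fell for 12 of 26, and 15 fell adjusted over the list alone (median -0.69, camera adjusted p = 5.83e-09, and adjusted p = 0.218 with an estimated correlation). An example was Cenpf (-1.35 ± 0.33). The median of -0.69 was -0.46 without C array 4. Ribosome biogenesis genes fell for 12 of 21, and 1 rose and 14 fell adjusted over the list alone (median -0.77, camera adjusted p = 1.04e-09). Among these were Npm1 (-1.37 ± 0.22) and Dkc1 (-1.38 ± 0.23). Heat shock genes fell for 7 of 9, also adjusted over the list alone (median -0.79, camera adjusted p = 2.47e-08). Examples were Hsp90aa1 (-1.14 ± 0.16) and Hspa8 (-1.11 ± 0.19). Oxidative phosphorylation genes fell for 10 of 24, and 11 fell adjusted over the list alone (median -0.37, camera adjusted p = 1.35e-06). Among these was Cox5a (-1.28 ± 0.13). With quantile normalization the median of -0.37 turned to 0.01 (adjusted p = 0.640). Glycolysis genes fell for 6 of 13 and rose for 2, and 2 rose and 6 fell adjusted over the list alone (median -0.39, camera adjusted p = 0.0146, and adjusted p = 0.149 with an estimated correlation). Among those that fell was Pgam1 (-1.04 ± 0.13). The list call was lost with quantile normalization (adjusted p = 0.162), and the median of -0.39 was -0.25 without C array 5. Immediate early genes fell for 7 of 20, and 1 rose and 7 fell adjusted over the list alone (median -0.54, camera adjusted p = 2.18e-04, and adjusted p = 0.326 with an estimated correlation). Among these was Fosb (-2.88 ± 0.75). With array weights the call was lost (adjusted p = 0.0692), and the median of -0.54 was -0.32 without B array 5. Scaling moved the sizes: with quantile normalization the medians were -0.24 for S phase, -0.36 for ribosome biogenesis and -0.25 for heat shock genes, and Hspa8, Hsp90aa1, Cox5a and Npm1 stood at -0.25, -0.67, -0.78 and -0.51. With median centring the medians were -0.99 for S phase, -1.11 for G2 and mitosis, -1.19 for ribosome biogenesis, -1.21 for heat shock, -0.80 for oxidative phosphorylation, -0.81 for glycolysis and -0.96 for immediate early genes. Ighm, the heavy chain of IgM, stood at -0.12 ± 0.31 on the probe set used and was not called. Of its 8 other probe sets 6 were called in the opposite direction, and with the mean of its probe sets it stood at 1.89.

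Between B and C 2746 genes passed, 1695 up and 1051 down, with 1030 and 292 of at least 2-fold. Of those that passed, 1390 had arrays that did not overlap. Among all 11947 genes tested this held for 1561, against a chance share of 0.253%. The direction depended on the scaling: the median of all genes was 0.19 as deposited, -0.23 with median centring and 0.01 with quantile normalization, and median centring gave 544 genes up and 2305 down, a share of higher genes of 19.1% in place of 61.7%. The share was 50.1% (1076 up and 1073 down) under the 75th percentile filter and 78.4% (2326 up and 642 down) with the mean of each gene's probe sets. Array weights gave 4610 genes. The Gapdh ratio was higher in B, that of actin was not, and the array medians were 69.7 to 92.7 in B and 100.6 to 153.1 in C. What part of the differences comes from this was not tested.

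**Figure D2:**
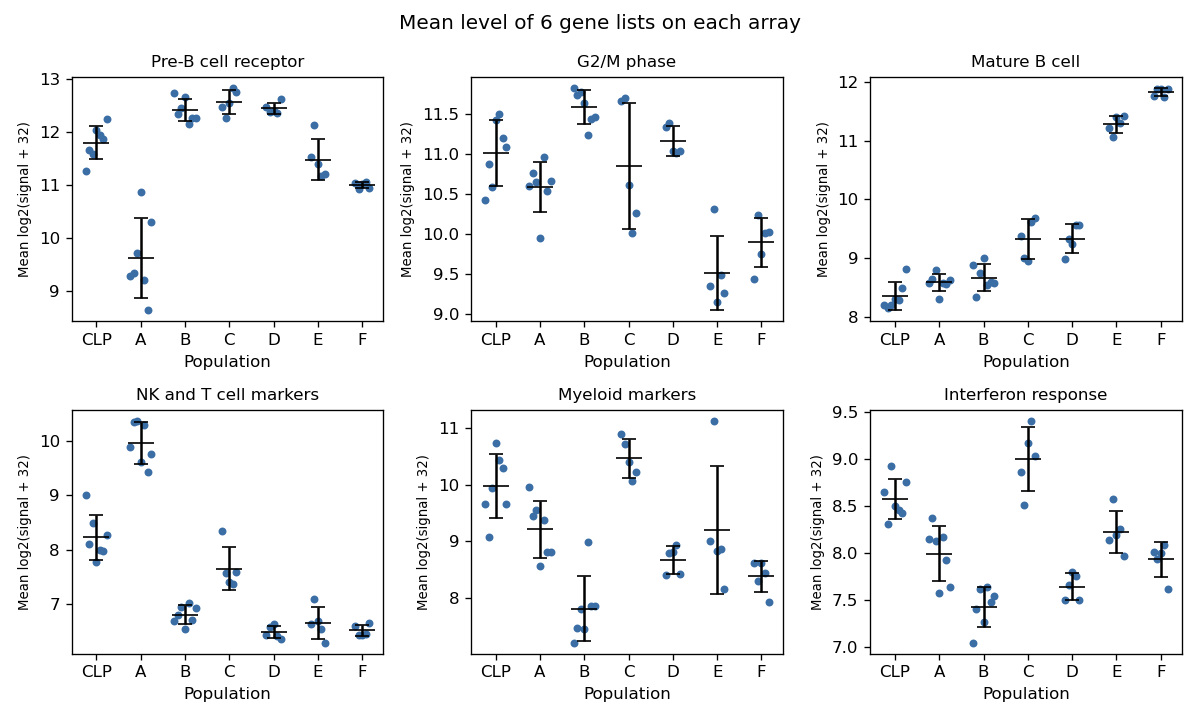
Mean log2 signal of the genes of 6 lists on each array (points) in the 7 populations, with the group mean and SD (bars); the panels show pre-B cell receptor, G2 and mitosis, mature B cell, NK and T cell, myeloid and interferon response genes. The NK and T cell level was highest in fraction A (9.96), and 1 array of E lay at 11.1 for the myeloid genes.

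Fraction D against fraction C compares small pre-B cells with late pro-B and large pre-B cells. Myc (-2.73 ± 0.24), a growth regulator on the interleukin 7 list, had a signal of 388 ± 158 (SD, n = 5) in D and 2737 ± 1006 (SD, n = 5) in C (limma adjusted p = 3.95e-11), and Ccnd2 (-2.59 ± 0.26), a cyclin of G1 on the same list, fell with it. The largest rises were Stfa3 (4.63 ± 0.68), Reln (4.45 ± 0.66), Fosb (3.69 ± 0.81), Fos (3.42 ± 0.56) and Trim72 (2.99 ± 0.56). The largest falls were Kbtbd11 (-4.96 ± 0.38), Gzma (-4.54 ± 0.53), Jchain (-3.90 ± 0.73), Mpeg1 (-3.72 ± 0.38) and Prkch (-3.64 ± 0.45). Among sorting markers Enpep (-2.69 ± 0.36) and Spn (-0.91 ± 0.20), which encodes CD43, fell, and Ptprc (0.72 ± 0.14) and Il7r (0.70 ± 0.18) rose.

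Of 15 interleukin 7 signalling genes 7 fell and 2 rose, also adjusted over the list alone (median -0.38, camera adjusted p = 0.0146, and adjusted p = 0.107 with an estimated correlation), and the call was lost in a fit of these 2 populations alone (adjusted p = 0.174). Cell cycle inhibitors rose for 7 of 12, also adjusted over the list alone (median 0.86, camera adjusted p = 6.60e-05). Examples were Klf2 (1.92 ± 0.50) and Rb1 (1.17 ± 0.21). Ribosome biogenesis genes fell for 11 of 21, also adjusted over the list alone (median -0.64, camera adjusted p = 3.44e-05, and adjusted p = 0.0597 with an estimated correlation). Among these were Nolc1 (-2.04 ± 0.24) and Fbl (-1.75 ± 0.24). Glycolysis genes fell for 6 of 13 and rose for 1, and 2 rose and 9 fell adjusted over the list alone (median -0.81, camera adjusted p = 0.0128, and adjusted p = 0.144 with an estimated correlation), with Pkm (-1.59 ± 0.28) and Aldoa (-1.27 ± 0.22) falling. That call was lost under the 75th percentile filter (adjusted p = 0.0531) and in a fit of these 2 populations alone (adjusted p = 0.0772). Immediate early genes rose for 11 of 20, and 12 rose adjusted over the list alone (median 1.05, camera adjusted p = 3.62e-07, and adjusted p = 0.149 with an estimated correlation). Genes of G2 and mitosis rose for 6 of 26, and 7 rose adjusted over the list alone (median 0.38, camera adjusted p = 0.00652, and adjusted p = 0.574 with an estimated correlation). Among these was Kif23 (1.66 ± 0.33). The 5 arrays of D (11.01 to 11.39) lay above C arrays 3, 4 and 5 (10.62, 10.02 and 10.26) and below C arrays 1 and 2 (11.66 and 11.69), so the rise held against 3 of the 5 arrays of C. Without C array 4 the median of 0.38 was 0.17 (adjusted p = 0.124), the call was lost without C array 5 (adjusted p = 0.0703), and by fry it was not made (adjusted p = 0.253). Early progenitor genes fell for 7 of 18 and rose for 1, and 2 rose and 8 fell adjusted over the list alone (median -0.71, camera adjusted p = 0.0282, and adjusted p = 0.450 with an estimated correlation), with Adgrg1 (-2.77 ± 0.26) and Ctla2a (-2.30 ± 0.40) falling. A pseudocount 4 times larger ended the call (adjusted p = 0.0560).

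Myeloid, interferon response, NK and T cell and plasmacytoid dendritic cell genes, all called higher in C than in B, were lower in D. Myeloid genes fell for 15 of 20, and 17 fell adjusted over the list alone (median -1.69, camera adjusted p = 1.97e-08, and adjusted p = 0.149 with an estimated correlation). Examples were Ltf (-2.98 ± 0.58) and Csf1r (-2.79 ± 0.76). Interferon response genes fell for 12 of 18, also adjusted over the list alone (median -1.47, camera adjusted p = 4.48e-07). Among these were Isg20 (-2.84 ± 0.46) and Ifit1 (-2.62 ± 0.45). NK and T cell genes fell for 8 of 18, and 1 rose and 8 fell adjusted over the list alone (median -0.81, camera adjusted p = 5.62e-04, and adjusted p = 0.144 with an estimated correlation). An example was Thy1 (-3.24 ± 0.34). Plasmacytoid dendritic cell genes fell for 7 of 14 and rose for 1, with the same counts adjusted over the list alone (median -0.97, camera adjusted p = 0.00275, and adjusted p = 0.107 with an estimated correlation). Among those that fell was Siglech (-3.55 ± 0.40). The other marker lists did not pass: erythroid genes, with 1 of 11 up and 2 down, also adjusted over the list alone (median -0.77, camera adjusted p = 0.488), plasma cell genes, with 2 of 12 up and 2 down, or 3 down adjusted over the list alone (median -0.11, camera adjusted p = 0.932), and megakaryocyte genes, with none of 6 called (median 0.11, camera adjusted p = 0.290).

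In total 2517 genes passed between C and D, 891 up and 1626 down, with 403 and 1103 of at least 2-fold, and 2125 had arrays that did not overlap, against a chance share of 0.794%. A fit of these 2 populations alone gave 5226 genes and array weights gave 5506.

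Fraction E against fraction D covers the step at which cells first carry a complete B cell receptor. The largest rise was that of Cd83 (4.71 ± 0.35), which had a signal of 2836 ± 599 (SD, n = 5) in E and 77.1 ± 19.2 (SD, n = 5) in D (limma adjusted p = 3.29e-13), and Bhlhe40 (4.63 ± 0.48), Egr3 (4.49 ± 0.41), Cxcr5 (3.91 ± 0.39), a homing receptor for B cell follicles, and Hivep3 (3.77 ± 0.47) made up the other largest rises. The largest falls were P2rx3 (-3.36 ± 0.45), Rbm24 (-3.26 ± 0.37), Rag2 (-3.17 ± 0.32), Vpreb1 (-2.98 ± 0.81), a surrogate light chain, and Erg (-2.88 ± 0.46). The call of Vpreb1 was lost without E array 4 (adjusted p = 0.0591). The receptor for interleukin 7, Il7r, fell by 2.33 ± 0.18, from 13085 ± 1008 (SD, n = 5) to 2698 ± 945 (SD, n = 5).

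Mature B cell genes rose for 17 of 22, and 19 rose adjusted over the list alone (median 1.86, camera adjusted p = 2.11e-27). MHC class II genes rose for 8 of 10, and 10 rose adjusted over the list alone (median 1.45, camera adjusted p = 9.79e-16). Examples were Cd74 (3.29 ± 0.43) and H2-DMb2 (3.08 ± 0.34). B cell receptor signalling genes rose for 5 of 21, and 8 rose adjusted over the list alone (median 0.51, camera adjusted p = 4.10e-05), Cr2 (2.30 ± 0.36) and Ptpn6 (2.28 ± 0.29), an inhibitory phosphatase, among them. NF-kappaB genes rose for 4 of 16, and 5 rose adjusted over the list alone (median 0.53, camera adjusted p = 2.94e-04). Examples were Cd40 (2.47 ± 0.53) and Icam1 (1.68 ± 0.33). Trafficking genes rose for 6 of 18 and fell for 2, also adjusted over the list alone (median 0.47, camera adjusted p = 1.23e-04). Ccr6 (2.74 ± 0.42) rose and Cxcr4 (-0.86 ± 0.24), a chemokine receptor, fell. Ribosome biogenesis genes rose for 2 of 21, and 6 rose adjusted over the list alone (median 0.35, camera adjusted p = 1.09e-04, and adjusted p = 0.0810 with an estimated correlation). Among these was Pes1 (0.86 ± 0.18). Interferon response genes rose for 3 of 18, and 4 rose adjusted over the list alone (median 0.61, camera adjusted p = 0.00128, and adjusted p = 0.0814 with an estimated correlation). Examples were Isg20 (1.79 ± 0.46) and Mx1 (1.58 ± 0.37). The 75th percentile filter ended the call (adjusted p = 0.0578). Immediate early genes rose for 3 of 20, and 3 rose and 1 fell adjusted over the list alone (median 0.32, camera adjusted p = 0.0196, and adjusted p = 0.502 with an estimated correlation). Among these was Egr1 (2.14 ± 0.51). Its call was lost without D array 3 (adjusted p = 0.0521), by fry (adjusted p = 0.103), under the 75th percentile filter and with the mean of each gene's probe sets.

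Proliferation genes fell: 23 of 26 genes of G2 and mitosis (26 fell adjusted over the list alone; median -1.72, camera adjusted p = 2.88e-34) and 15 of 26 S phase genes (20 fell adjusted over the list alone; median -0.96, camera adjusted p = 6.70e-21). Examples were Bub1 (-2.10 ± 0.28), Ect2 (-2.09 ± 0.31) and Uhrf1 (-1.65 ± 0.20), and the chromatin regulator Ezh2 (-1.75 ± 0.15) also fell. V(D)J recombination genes fell for 6 of 13, also adjusted over the list alone (median -0.66, camera adjusted p = 1.24e-06), among them Dntt (-3.09 ± 0.50), which adds bases at the joins. Pre-B cell receptor genes fell for 4 of 11, and 5 fell adjusted over the list alone (median -0.76, camera adjusted p = 7.90e-04, and adjusted p = 0.108 with an estimated correlation). Among these was Igll1 (-2.97 ± 0.59). Sorting markers moved both ways, with 2 of 10 up and 4 down, and 2 rose and 4 fell adjusted over the list alone: Ly6d (1.38 ± 0.27) and Ptprc (0.61 ± 0.14) rose, and Enpep (-2.43 ± 0.36) and Cd93 (-1.15 ± 0.21) fell. The mean of that list was -0.43, and the test gave a fall (median 0.12, camera adjusted p = 0.0445, and adjusted p = 0.0990 with an estimated correlation). The result was lost without D array 5 (adjusted p = 0.0601) or E array 1 (adjusted p = 0.0517), and the median was 0.18 without D array 2, 0.04 without D array 3 and -0.07 without E array 2. Most alternatives also ended this call, with an adjusted p up to 0.621 in a fit of these 2 populations alone, the mean of each gene's probe sets turned the median to -0.02, and quantile normalization gave a median of 0.02. Array 2 of fraction E held other signals beside these: its myeloid level was 11.1 against a mean of 8.72 on the other 4 arrays of E, 19 of 20 myeloid genes were at least 1 higher there on the log2 scale, and its level for G2 and mitosis genes was 10.3 against 9.16 to 9.49. No myeloid gene passed in E vs D. The list was called up (median 0.50, camera adjusted p = 0.0194, and adjusted p = 0.558 with an estimated correlation), but without that array the median was 0.04 (adjusted p = 0.777). It was also lost by fry (adjusted p = 0.211), with array weights, under the 75th percentile filter and in a fit of these 2 populations alone. The early progenitor list had 5 of 18 members up, 5 rose and 1 fell adjusted over the list alone, and Lmo2 (2.57 ± 0.37) rose.

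Between D and E 968 genes passed, 465 up and 503 down, with 339 and 373 of at least 2-fold, and 920 had arrays that did not overlap, against a chance share of 0.794%. A fit of these 2 populations alone gave 2995 genes and array weights gave 3161. The count was 892 without the 572 genes that were at least 1 higher in E array 2 than on the other arrays of E.

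Fraction F against fraction E compares recirculating mature B cells with newly formed ones. Few genes passed in the fit of all populations. Gimap4 (3.10 ± 0.32), a GTPase of lymphocytes, rose to 3707 ± 792 (SD, n = 5) in F from 401 ± 58.1 (SD, n = 5) in E (limma adjusted p = 3.54e-08). The other largest rises were Clec2i (2.22 ± 0.38), Pcp4 (2.16 ± 0.39), Pgap1 (2.15 ± 0.29) and Nid1 (2.09 ± 0.40). With a pseudocount of 1 the calls of Pcp4 and Nid1, which have low signals in E, were lost (adjusted p = 0.199 and 0.115). The largest falls were Rem2 (-3.02 ± 0.44), Rapgefl1 (-1.97 ± 0.36) and Efnb2 (-1.81 ± 0.41). The remaining 2 of the 5 largest lost their calls when single arrays were left out and are not named. Efnb2 too rested on few arrays: its call was lost without E array 3 or 4 or F array 5 (adjusted p = 0.0813, 0.0709 and 0.135). Cd93, a marker of immature B cells, fell by 1.10 ± 0.21.

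MHC class II genes rose for 2 of 10 over all genes tested, while 7 rose adjusted over the list alone (median 1.02, camera adjusted p = 9.59e-17). Among these was H2-Ab1 (1.39 ± 0.27). Mature B cell genes rose for 2 of 22, and 5 rose adjusted over the list alone (median 0.46, camera adjusted p = 1.18e-08): Fcer2a (1.67 ± 0.33), which encodes CD23 and was lost with a pseudocount of 1 (adjusted p = 0.269), and Bcl2 (1.27 ± 0.28), a survival gene, which was lost with median centring (adjusted p = 0.0806). Trafficking genes rose for 1 of 18, and 3 rose adjusted over the list alone (median 0.21, camera adjusted p = 2.38e-04), namely Itgb7, an integrin chain, from 389.5 ± 90.4 (SD, n = 5) to 1142 ± 121 (SD, n = 5). B lineage transcription factors fell for 2 of 19, and 3 fell adjusted over the list alone (median -0.28, camera adjusted p = 0.0123, and adjusted p = 0.215 with an estimated correlation), Sox4 (-1.16 ± 0.24) among them (adjusted p = 0.478 with the mean of its probe sets). By fry the adjusted p was 0.106. Pre-B cell receptor genes fell for 1 of 11, and 2 fell adjusted over the list alone (median -0.31, camera adjusted p = 0.00405, and adjusted p = 0.169 with an estimated correlation). By fry the adjusted p was 0.0949. No gene of G2 and mitosis passed, also adjusted over the list alone. That list stood higher in F (median 0.38, camera adjusted p = 4.48e-07, and adjusted p = 0.314 with an estimated correlation), or 0.57 without E array 2, and by fry the adjusted p was 0.209. No myeloid gene passed, also adjusted over the list alone, and that list stood lower (median -0.86, camera adjusted p = 1.18e-08, and adjusted p = 0.144 with an estimated correlation), or -0.38 without E array 2. By fry the adjusted p was 0.0572. No erythroid gene passed over all genes tested, 4 fell adjusted over the list alone, and the list stood lower (median -0.86, camera adjusted p = 4.60e-06, and adjusted p = 0.0810 with an estimated correlation), or at -0.34 without that array. The sorting markers stood lower, with 2 of 10 down, also adjusted over the list alone (median -0.21, camera adjusted p = 0.0375, and adjusted p = 0.0867 with an estimated correlation). Without E array 2 the median was -0.08 (adjusted p = 0.241). It was also lost with the mean of each gene's probe sets (adjusted p = 0.109), median centring, array weights and the 75th percentile filter.

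In total 56 genes passed between E and F, 31 up and 25 down, with 27 and 20 of at least 2-fold. An unadjusted p under 0.05 was found for 733, and 51 of those that passed had arrays that did not overlap, against a chance share of 0.794%. The count was 572 in a fit of these 2 populations alone and 467 with array weights, and it was 33 without E array 4. The split was 208 up and 259 down with array weights (44.5% up), 28 and 13 without E array 2 (68.3%) and 22 and 11 without E array 4 (66.7%), in place of 55.4%.

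Fraction F against the CLP sets the ends of the path against each other. Genes of mature B cells were far higher in F: Ms4a1 (7.55 ± 0.41), which encodes CD20, had a signal of 21173 ± 1074 (SD, n = 5) in F and 113 ± 117 (SD, n = 7) in the CLP (limma adjusted p = 1.59e-18). The latter was at the array medians, and the difference was 8.20 with a pseudocount of 1 and 6.59 with a pseudocount 4 times larger. The other largest rises were Scd1 (6.10 ± 0.38), a fatty acid desaturase, Cd55 (5.85 ± 0.45), Fcmr (5.83 ± 0.38), a receptor for IgM, and 4930426D05Rik (5.81 ± 0.32). The largest falls were Dntt (-7.12 ± 0.46), Jchain (-6.44 ± 0.68), Adgrg3 (-6.27 ± 0.39), Hoxa9 (-6.17 ± 0.53), a transcription factor of early progenitors, and Gfra2 (-5.92 ± 0.53). Dntt, the enzyme that adds bases at V(D)J joins, had a signal of 15749 ± 2525 (SD, n = 7) in the CLP and 87.4 ± 49.4 (SD, n = 5) in F. Among sorting markers, Flt3 (-5.05 ± 0.43) and Kit (-3.39 ± 0.47), growth factor receptors of progenitors, fell, as did Il7r (-2.48 ± 0.17), Cd93 (-2.46 ± 0.20) and Spn (-1.98 ± 0.18), and Ptprc (1.41 ± 0.13) and Cd24a (0.89 ± 0.21) rose, the last by 0.33 with quantile normalization.

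Mature B cell genes rose for 20 of 22 and fell for 1, and 20 rose and 1 fell adjusted over the list alone (median 3.82, camera adjusted p = 5.04e-24). MHC class II genes rose for 9 of 10, also adjusted over the list alone (median 2.59, camera adjusted p = 1.23e-11). An example was H2-Aa (4.27 ± 0.31). B cell receptor signalling genes rose for 14 of 21 and fell for 2, and 15 rose and 2 fell adjusted over the list alone (median 1.26, camera adjusted p = 2.47e-08). Examples were Cd22 (5.44 ± 0.39) and Cr2 (4.14 ± 0.33). NF-kappaB genes rose for 9 of 16 and fell for 1, also adjusted over the list alone (median 0.83, camera adjusted p = 3.58e-05). Among those that rose were Cd40 (4.38 ± 0.49) and Rel (2.30 ± 0.28). Immediate early genes rose for 15 of 20 and fell for 1, and 16 rose and 1 fell adjusted over the list alone (median 1.16, camera adjusted p = 1.47e-06, and adjusted p = 0.170 with an estimated correlation). Among those that rose was Egr3 (5.29 ± 0.38). CLP array 7 (10.98) lay within the range of F (10.65 to 11.20), and the other CLP arrays lay below it (8.85 to 10.33). Cell cycle inhibitors rose for 6 of 12 and fell for 3, and 7 rose and 3 fell adjusted over the list alone (median 0.72, camera adjusted p = 0.0292, and adjusted p = 0.223 with an estimated correlation). Btg1 (2.04 ± 0.20) rose and Cdkn1a (-3.38 ± 0.48) fell, and the call was lost with no filter on low values (adjusted p = 0.0710) and in a fit of these 2 populations alone (adjusted p = 0.0510).

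Early progenitor genes fell for 13 of 18, and 2 rose and 13 fell adjusted over the list alone (median -1.90, camera adjusted p = 5.58e-06, and adjusted p = 0.0990 with an estimated correlation). S phase genes fell for 20 of 26, also adjusted over the list alone (median -1.05, camera adjusted p = 1.96e-06), and genes of G2 and mitosis for 22 of 26, where 23 fell adjusted over the list alone (median -1.11, camera adjusted p = 6.04e-05, and adjusted p = 0.442 with an estimated correlation). Examples were Gins2 (-2.83 ± 0.34) and Bub1b (-2.49 ± 0.31). Cholesterol synthesis genes fell for 12 of 18, also adjusted over the list alone (median -0.79, camera adjusted p = 0.00972, and adjusted p = 0.0597 with an estimated correlation), among them Sqle (-2.78 ± 0.30) and Fdft1 (-1.97 ± 0.30), enzymes of the path through squalene. Glycolysis genes fell for 9 of 13 and rose for 1, also adjusted over the list alone (median -0.85, camera adjusted p = 0.0170, and adjusted p = 0.161 with an estimated correlation). Among those that fell was Pkm (-1.89 ± 0.26). The 75th percentile filter ended the call (adjusted p = 0.0694). Oxidative phosphorylation genes fell for 11 of 24 and rose for 1, and 1 rose and 11 fell adjusted over the list alone (median -0.46, camera adjusted p = 0.0282, and adjusted p = 0.341 with an estimated correlation). Among those that fell was Cyc1 (-1.46 ± 0.22). This call was lost without F array 1 (adjusted p = 0.0558), with median centring (adjusted p = 0.0538) and under the 75th percentile filter (adjusted p = 0.0616). Interleukin 7 signalling genes fell for 7 of 15 and rose for 2, and 2 rose and 8 fell adjusted over the list alone (median -0.73, camera adjusted p = 0.0391, and adjusted p = 0.170 with an estimated correlation), with Socs2 (-3.13 ± 0.42) and Ccnd3 (-2.84 ± 0.23) falling. The list call was lost without CLP array 1 (adjusted p = 0.0507), with the mean of each gene's probe sets (adjusted p = 0.211), under the 75th percentile filter, with array weights and in a fit of these 2 populations alone. Of the 6 marker lists of other cell types 2 passed, both lower in F: 12 of 18 NK and T cell genes fell and 1 rose, also adjusted over the list alone (median -1.56, camera adjusted p = 1.71e-04, and adjusted p = 0.107 with an estimated correlation), with Thy1 (-5.21 ± 0.32) falling, and 12 of 20 myeloid genes fell, also adjusted over the list alone (median -1.32, camera adjusted p = 7.90e-04, and adjusted p = 0.439 with an estimated correlation). Among these were Csf1r (-4.52 ± 0.71) and Ctsg (-4.05 ± 0.53). Plasmacytoid dendritic cell genes fell for 7 of 14 and rose for 1, and 1 rose and 8 fell adjusted over the list alone, but the list did not pass (median -0.71, camera adjusted p = 0.0648). It passed with no filter (adjusted p = 0.00663), the 75th percentile filter (median -1.26, adjusted p = 0.0375), the mean of each gene's probe sets (adjusted p = 0.0185), the replicate number as a block (adjusted p = 0.0445), fry (adjusted p = 2.46e-06) and without CLP array 5 (adjusted p = 0.0492). Erythroid genes fell for 5 of 11, and 6 fell adjusted over the list alone, without the list passing (median -1.08, camera adjusted p = 0.182), except with no filter (adjusted p = 0.0342) and by fry (adjusted p = 0.00680). The sorting markers had 6 of 10 down and 2 up, and 3 rose and 6 fell adjusted over the list alone.

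Between the CLP and F 4993 genes passed, 1817 up and 3176 down, with 953 and 2059 of at least 2-fold, and 3844 had arrays that did not overlap, against a chance share of 0.253%. On the probe set used Ighm stood at 0.14 ± 0.31 and was not called, while 6 of its 8 other probe sets were called lower in F. With the mean of its probe sets it stood at -2.54.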

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

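In 33 measures of the 7 populations, 231 groups of values, each group was searched for a single array apart from the rest with Dixon's test; chance gives about 1 in 20 groups, or 11.55, and 27 were found. Single genes were not examined this way. List values are mean log2 levels. Array 2 of fraction E held the most of these: its myeloid level was 11.14 (others up to 9.01), G2 and mitosis 10.32 (up to 9.49), S phase 10.88 (up to 10.50), V(D)J recombination 9.86 (up to 9.43), glycolysis 10.62 (up to 10.27) and sorting markers 10.87 (up to 10.49). Its MHC class II level was low at 10.81 (others from 11.16), and its mean correlation with its group was low at 0.953 (others from 0.963).

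Among other lists, the myeloid level was high on B array 5 at 8.98, the erythroid level on CLP array 6 at 10.67 and A array 1 at 9.24, the megakaryocyte level on D array 5 at 8.07 and F array 2 at 7.69, and both the NK and T cell level (8.34) and the plasma cell level (11.04) on C array 1. CLP array 7 was high for MHC class II at 9.99 and apoptosis at 10.07, D array 4 for cell cycle inhibitors at 11.17 and A array 7 for ribosome biogenesis at 11.57. Low values were B cell receptor signalling on A array 6 at 9.12, G2 and mitosis on A array 4 at 9.95, cholesterol synthesis on C array 5 at 9.13, heat shock on D array 2 at 12.19 and apoptosis on E array 5 at 9.44. The 3' to 5' Gapdh ratio was 33.8 on A array 4 (others up to 16.7), the median signal 132.9 on F array 1 (others up to 120.8), and the mean correlation of F array 1 with its group 0.946 (others from 0.951).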

How the results depend on the processing

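Leaving out sets of arrays or 572 genes high in E array 2 was chosen after seeing the data, the rest before. Of 10746 comparisons of named genes, 10306 gave the same call, 321 a weaker, 105 a stronger and 14 a reversed value. Of 2611 for lists 2407 were the same, 170 weaker, 34 stronger and 0 reversed. Of the first, 5134 left out 1 array and 182, all the same, left out genes, so the total overstates agreement. Quantile normalization turned Sec11c to -0.033 in A vs CLP and 0.12 in C vs B, and Atp5a1 to -0.15 in F vs CLP. The mean of a gene's probe sets turned Cd247 to -1.06 in B vs A and -0.76 in F vs CLP, Ptpn11 to 0.0034 in B vs A, Ighm to 1.89 in C vs B, -1.60 in D vs C and -2.54 in F vs CLP, Sec11c to 0.43 in C vs B and Pik3cd to 0.22 in F vs CLP. In A vs CLP Crebbp stood at 0.0049 with array weights and 0.053 without A arrays 4, 6 and 7, which gave -0.34 in B vs A. Tested singly, 8204, 6564, 5101, 4460, 1595 and 9089 probe sets passed in A vs CLP, B vs A, C vs B, D vs C, E vs D and F vs CLP, and 16824 across the populations. A fit of the 2 groups alone gave 2418, 1343, 5226, 2995 and 572 genes for A vs CLP, B vs A, D vs C, E vs D and F vs E. Array weights gave 4610, 5506, 3161 and 467 from C vs B to F vs E, but 20.1% to 26.5% of calls were false with them in simulated data of these comparisons. With the fit of the 2 groups alone 2.46% to 7.86% were false there. Few genes were changed in the simulated data, so these shares do not carry over to the real counts. With an estimated correlation 35 list tests passed in place of 89. Quantile normalization gave 4021, 3693, 1881, 2963, 1252, 81 and 5365 genes in the order of the report, and 95 list tests. With 1 array left out the counts ran from 4054 to 4685 (A vs CLP), 3309 to 3982 (B vs A), 2067 to 2701 (C vs B), 1969 to 2449 (D vs C), 811 to 902 (E vs D), 33 to 49 (F vs E, lowest without E array 4), 4488 to 4853 (F vs CLP) and 8540 to 9090 (all 7), and 84 to 92 list tests passed. Without A arrays 4, 6 and 7, 3648 (A vs CLP) and 3701 (B vs A) genes passed; without B arrays 1 and 4, 3819 (B vs A) and 2482 (C vs B). List calls not described above because single arrays ended them were early progenitor genes in C vs B and E vs D, sorting markers in F vs CLP and apoptosis in F vs E. The arrays carry equal replicate numbers across populations, and in 5 of the comparisons 0 to 2 arrays were closest to the array with their own number. In E vs D and F vs E, 4 arrays each were closest to the array with their own number; the cause was not tested. With the replicate number as a replicate block 4480, 3785, 2796, 2569, 1001, 59 and 5008 genes passed. Signal over background limits the low genes: a pseudocount shrinks their differences, and none of the alternatives removes background.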

Other observations

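The series notes that genes expressed in these progenitors are also altered in hypodiploid acute lymphoblastic leukaemia, and 13 of 18 listed genes of that disease were tested here. Across the 7 populations 12 of the 13 differed by the limma F-test after adjustment, as did 73.3% of all genes tested. Flt3 was highest in the CLP, with a signal of 2336 ± 432 (SD, n = 7), and lowest in D, with 33.5 ± 17.5 (SD, n = 5) (adjusted p = 4.46e-16). Ikzf2 went from 476 ± 199.6 (SD, n = 7) in the CLP to 21.8 ± 20.4 (SD, n = 5) in D. Pax5 was highest in C, with 2629.8 ± 427 (SD, n = 5), and lowest in A, with 122 ± 151 (SD, n = 7) (adjusted p = 1.83e-16). The low signals lay under the array medians for Flt3 and Ikzf2 and among them for Pax5 and Nf1, so no fold is given. Etv6 was highest in the CLP, with a range of 7.22-fold down to F, whereas Ikzf3, a zinc finger factor of lymphocytes, was highest in F, 9.13-fold above the CLP. These folds were taken on the values with 32 added. Rb1 (3.32-fold), Crebbp (2.00-fold), Ezh2 (3.35-fold) and Ikzf1 (1.69-fold) were highest in D, and Pag1 (3.23-fold) in E. Without A arrays 4, 6 and 7 Crebbp was not low in A (A vs CLP 0.053). Its D vs C call was lost in 9 fits without an array. Ptpn11 (2.61-fold) and Nf1 (adjusted p = 0.0418) were highest in C. The mean of its probe sets ended the Ptpn11 calls in C vs B, D vs C and F vs CLP. Nras, with a 1.40-fold range, did not pass (adjusted p = 0.102). As a list these genes passed only in F vs E, where no member was called, also adjusted over the list alone (median -0.21, camera adjusted p = 0.0192, and adjusted p = 0.105 with an estimated correlation; adjusted p = 0.187 with the mean of each gene's probe sets).

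Notch pathway genes, which direct early lymphoid cells away from the B lineage, passed as a list in no comparison; in A vs CLP 1 of 10 rose and 4 fell, with the same counts adjusted over the list alone (median -0.38, camera adjusted p = 0.560). Between the ends of the path, apoptosis genes went both ways: 4 of 14 rose and 4 fell in F vs CLP, where 5 rose and 4 fell adjusted over the list alone (median 0.02, adjusted p = 0.517). Mcl1 (1.54 ± 0.21), a survival gene, rose. Megakaryocyte genes did not pass in F vs CLP either, with 2 of 6 down, also adjusted over the list alone (median -0.08, adjusted p = 0.529). Plasma cell genes had 3 of 12 up and 5 down, with the same counts adjusted over the list alone (median -0.33, adjusted p = 0.525). By fry, which asks whether the genes of a list moved and not whether they moved more than others, the adjusted p was 8.53e-05 for Notch genes in A vs CLP, and 0.623, 0.00798 and 0.00352 for apoptosis, megakaryocyte and plasma cell genes in F vs CLP.

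For each count of genes the arrays were split in 100 ways, the real one included. In each case only the real split gave as many genes, the lowest share 100 splits allow. The arrays may be technical repeats, so chance is not excluded. The real count and the highest of the other splits were 4424 and 2858 for A vs CLP, 3741 and 2798 for B vs A, 2746 and 1405 for C vs B, 2517 and 231 for D vs C, and 968 and 171 for E vs D. They were 56 and 0 for F vs E, 4993 and 2495 for F vs CLP and 8756 and 42 across the 7 populations. The many genes in other splits of the comparisons that use the CLP, A or B may come from splits that kept much of the real grouping or from structure among the arrays, which was not tested.

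The tests of the 3 patterns weighed here were chosen only after the results were seen, while the counts of other splits were planned. Genes of NK and T cells were higher in fraction A than in the CLP, with a list median of 1.18. A lower share of the main cell type would raise all other markers if the rest gained alike. Plasmacytoid dendritic cell genes rose, but 10 of 20 myeloid genes fell and 2 rose (median -1.05, camera adjusted p = 0.300). The rest need not gain alike, and 9 of 11 pre-B cell receptor genes fell, so this stays open. Without the 3 arrays of A with the lowest correlation the NK and T cell median was 1.44, which argues against that source. The T cell gene Gata3 fell by 1.73, so a change in NK cells rather than T cells, in number or state, may underlie the rise, and the labels do not give the gates that would exclude them.

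Myeloid genes were higher in fraction C than in B, and RNA of myeloid cells in the sorted fraction is a candidate source that stays open: 16 of 20 myeloid genes rose, but this count restates the pattern and decides nothing. No level that the source would need was set. No gene of the list is in another list, and how many of them B cell precursors express was not tested. A lower share of the main cell type cannot be told apart from this, since 2 of the 5 other marker lists were also called up with the deposited scaling, and the erythroid list passed as well with quantile normalization (adjusted p = 0.0137) and median centring (adjusted p = 0.00566). A gate against myeloid cells would remove it, but the labels do not give the gates.

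Interferon response genes were higher in C than in B by a median of 1.34. The scaling of the arrays could raise any list, since it moved the median of all genes, but the lower of the list medians under quantile normalization and median centring was 0.92, and both passed, which argues against the scaling as the whole cause. Within C the myeloid and interferon levels did not move together. Arrays 1 and 2 had the highest myeloid (10.90 and 10.73) and the lowest interferon levels (8.86 and 8.51). On E array 2 both were the highest of E, above the others by a median of 2.38 for myeloid but 0.22 for interferon genes. These levels rest on few arrays and were not tested, and myeloid cells, plasmacytoid cells and a response of the B lineage cells stay open. No biological explanation was tested for any of the 3 patterns, since the design varies only the population.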
